A study of Rattus norvegicus with 8 samples.

How the data were processed

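Total RNA from the whole medial prefrontal cortex of 4 control and 4 JFLX rats was labelled from 500 ng with the Agilent Quick-Amp kit and hybridised with Cy3 to custom Agilent rat arrays, per the labels' protocols. The deposited value table holds log2 values in which the median of the 4 control arrays is 0 at each of the 15207 probes, so the level of a probe is centred out and only differences between arrays remain. The authors' lists of higher and lower probes give the background-subtracted linear intensity of each probe on each array, per the file headers. They also give the authors' log2 group means, which match the means of the value table, and a p-value whose test is not named in the deposited table; it equals that of an equal-variance t-test on the same values within a relative difference of 7.91e-07. Counts of arrays flagged as detected complete the authors' table. Over the 582 listed probes the difference between log2 intensity and deposited log2 value was a constant shift of -0.18 between the groups, so the between-array normalization acts as an additive constant per group mean; its name, the scanner software and the background method are not given in the sources used here. The authors listed a probe when its mean JFLX value was at least 0.4 or at most -0.4, its p at most 0.05 and its flag detected in at least 3 or 4 arrays of the JFLX (higher) or control (lower) group, per the read-me sheet. In each list 16 further columns of folds and flags per array were not used here, and columns of intensity were assigned to groups only.

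All 8 arrays were on 1 slide, and the read-me sheet places the control arrays in one position block and the JFLX arrays in the other. Position on the slide and treatment cannot be told apart. No control spots were removed because none were marked in the value table, and 0 values were missing.

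Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend), two-sided, with Benjamini-Hochberg adjustment over all 15207 probes and a threshold of 0.05. Folds are JFLX against control, SE is the moderated standard error and n is 4 per group. On simulated arrays with the residual spread of this comparison and its 15207 probes, with 200 changed probes in each of 10 draws, the fit recovered 19.0% of 1.5-fold, 50.8% of 2-fold, 80.2% of 4-fold and 90.2% of 8-fold changes, and 6.6% of its calls were false. Noise was drawn independently for each simulated probe, whereas many real probes vary together, so these rates may not carry over to the real calls. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for tables, Fisher's exact tests and plots.

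Gene names were available only for the 582 listed probes. Of these, 551 were named through their gene ID in a RefSeq table of the assembly GRCr8, whose coordinates were not used, and 31 kept the name in the file. A symbol was found for 565 probes, or 530 genes, and the other 14625 probes of the array are unnamed here. A gene with several listed probes is represented by its probe that comes earliest in the table. A probe detected on 0 arrays of a group has only a bound there: the mean log2 control signal was set against the mean, over the JFLX arrays, of the higher of the lowest detected signal and the probe's own signal, after the normalization shift, and no fold is given where that bound is under 1. Lowest detected signals were taken over the listed probes detected on all 4 arrays of a group.

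The rule for named genes was fixed before the data were examined. It takes the 12 genes with the largest fold in each direction past the threshold with groups that do not overlap, up to 4 members of each gene list by p, a set of 8 fixed genes of serotonin signalling, growth factors, mitochondria and interneurons, and the 10 largest folds per direction of the authors' deposited table. None of those 8 genes is among the named probes, so they are not reported here. Some genes that the rule takes in the lower direction are not reported here either. The 23 gene lists and 12 marker lists were to be tested with camera at a preset correlation of 0.01. That test needs names for all probes and was replaced, after seeing the data, by counts of listed members and Fisher's exact test of their higher to lower split against the other listed genes.

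Alternatives fixed beforehand were quantile normalization, centring on the median or the 75th percentile, eBayes with trend and robust, array quality weights, a replicate block, an equal-variance t-test, averaging the probes of a gene, leaving out each array, and restricting the authors' table to folds of at least 2. Filters on dim probes could not be run on centred values. Leaving out the unlisted probes of the authors' fold and p, with and without quantile normalization, and leaving out the probes of a shared profile were added after seeing the data.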

Results

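Gene expression was measured in the whole medial prefrontal cortex of rats at 6 months of age, long after a drug course given in the juvenile period. The treated group, called JFLX, received fluoxetine, a serotonin reuptake inhibitor used as an antidepressant, at 10 mg/kg from postnatal day 28 to day 48. The control group received the 5% sucrose vehicle over the same days. Each group holds 4 samples, hybridised with a single dye (Cy3) to custom Agilent rat arrays, and 15207 probes carry a value on all 8 arrays. Among the 582 probes that the authors listed as changed, the median background-subtracted intensity ran from 36.7 to 51.0 over the control arrays and from 32.5 to 63.5 over the JFLX arrays. For arrays the number of samples limits the precision. The labels do not say that each sample came from a separate animal, so p-values measure only the spread between these samples. The free-text descriptions of control replicates 2 to 4 speak of fluoxetine, whereas their titles, source names and the treatment protocol place them in the vehicle group, and the grouping here follows the latter.

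The comparison asks which transcripts differ in the adult cortex after juvenile fluoxetine. The largest increase among named genes was that of Gsk3a, a glycogen synthase kinase, which was higher in JFLX by 1.63 ± 0.16 on the log2 scale (SE, n = 4 per group), a 3.10-fold difference. Ppp2r2c, a regulatory subunit of a serine/threonine phosphatase, rose by 1.40 ± 0.15, and the kinase Stk32c rose by 1.36 ± 0.13. The RNA helicase Ddx6 rose by 1.35 ± 0.16 and the spliceosome component Prpf8 by 1.32 ± 0.13. Vdac1, a channel of the outer mitochondrial membrane, rose by 1.16 ± 0.12, and the sialyltransferase St3gal1 by 1.25 ± 0.20. The metallophosphoesterase Mpped1 rose by 1.25 ± 0.13, Tollip, an adaptor of Toll-like receptor signalling, by 1.16 ± 0.15, Dcbld1 by 1.17 ± 0.17, the actin-binding coronin Coro1c by 1.15 ± 0.26 and the pseudogene Lin9-ps1 by 1.47 ± 0.28. As their selection required, the 4 JFLX arrays lay above the 4 control arrays in all 12 of these genes. Their limma adjusted p ran from 0.00252 for Gsk3a to 0.0376 for Coro1c, which did not pass in 15 of the 19 other settings. The Gsk3a probe lies on chromosome 1 from 80584935 to 80585081, the Prpf8 probe on chromosome 10 from 62835935 to 62835994 and the Vdac1 probe on chromosome 10 from 37828742 to 37828801, in positions of the deposited table whose genome build is not given in the sources used here.

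**Figure D1:**
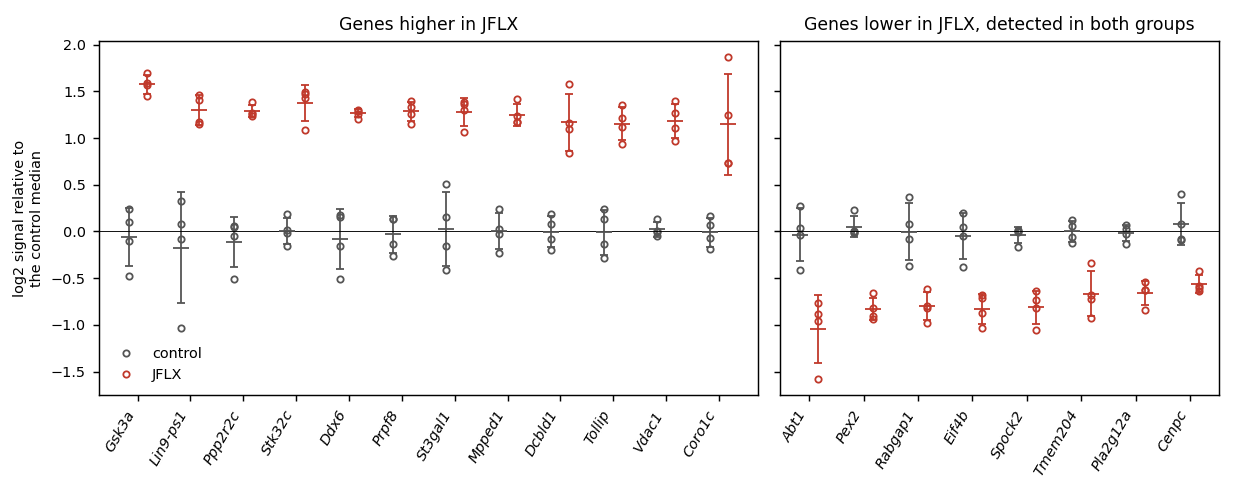
Log2 signal relative to the control median (y axis) for the 12 genes with the largest increases and 8 lower genes detected in both groups, with open circles for single arrays (4 control in grey, 4 JFLX in red) and bars for the group mean and SD. JFLX arrays sit above control for Gsk3a (mean 1.57 against -0.06) and below it for Pex2 (mean -0.83 against 0.05).

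Over all probes, 950 passed an adjusted p of 0.05 in limma, 896 higher and 54 lower in JFLX, so that 94.3% of the calls were higher. With each array centred on its 75th percentile, which moves the median difference of all probes by -0.19, the split was 682 higher and 221 lower. At an unadjusted p under 0.05, 2350 probes differed against 760 expected by chance on average, and 1603 of them reached 1.5-fold, 1405 higher and 198 lower. Probes vary together, and over the other splits of the arrays into 4 and 4 the unadjusted count ran from 166 to 1718. The 2 groups did not overlap at 1973 probes, where chance gives 2.86% of the 15207, or 434. Of the 950 probes, 796 carry no gene name here, and 790 of those belong to a set of 1088 probes that met the authors' fold and p in the higher direction and yet are absent from their list of higher genes. By the authors' stated rule, such probes would be left off for lacking the detected flag on enough JFLX arrays. Flags of unlisted probes were not seen here, so most of the higher calls rest on probes not known to be detected in JFLX. When these 1088 probes and the 29 lower ones of the same kind were left out, a setting chosen after seeing the data, 6 probes passed in limma, those of Gsk3a, Ppp2r2c, Stk32c, Prpf8, Mpped1 and Vdac1, with 1248 at an unadjusted p under 0.05, but leaving out probes with small p-values raises the other adjusted p-values by construction. Quantile normalization left 0 probes past the limma threshold, with 1298 at an unadjusted p under 0.05. None of the other named genes passed in either of these settings. Quantile normalization was run on values already centred on the control median. Their SD was 0.35 to 0.52 over the control arrays and 0.64 to 0.74 over the JFLX arrays. Forcing all arrays to the same distribution removes this difference in spread by construction, so the 0 cannot decide whether the calls hold.

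Among genes detected above background on at least 3 arrays of both groups, 20 named genes passed the test in the lower direction. The largest of these decreases, chosen after their values were seen, were Abt1, an activator of basal transcription, which fell by 1.01 ± 0.22 (SE, log2), and Pex2, a peroxisome biogenesis factor, which fell by 0.88 ± 0.11. The GTPase-activating protein Rabgap1 fell by 0.80 ± 0.17, the translation initiation factor Eif4b by 0.78 ± 0.15 and Spock2, a proteoglycan of the extracellular matrix, by 0.77 ± 0.12. Tmem204, the phospholipase Pla2g12a and the centromere protein Cenpc fell by 0.67 ± 0.14, 0.64 ± 0.10 and 0.64 ± 0.13, and the adjusted p of these 8 genes ran from 0.00252 for Pex2 to 0.0322 for Abt1. Over the 19 other settings, Rabgap1 and Tmem204 did not pass in 13, Abt1 in 12, Cenpc in 10 and Eif4b in 9. Of the 2 listed probes of Tmem204, which share a sequence, only 1 passed in the main fit. Among the genes with the largest fitted decreases past the threshold were Ube2c, Usp28, Bhlha15, Zfp143, Btg4, Ripk4, Loxl3, Abt1, Itpr2 and Or14c39, with adjusted p from 0.00557 for Zfp143 to 0.0394 for Ripk4. Over the 19 other settings Ripk4 did not pass in 13, Usp28 and Btg4 in 12, Ube2c in 11, Or14c39 in 9, Itpr2 in 7, Loxl3 in 5 and Bhlha15 and Zfp143 in 4. All of them except Abt1 were not well above background on any JFLX array. No fold is given for these genes, because their mean control signal did not exceed the lowest detected signals of the JFLX arrays. Btg4 too has 2 listed probes that share a sequence, of which only 1 passed. The count of 54 lower probes was 0 with trend and robust in eBayes, 21 with a replicate block, 19 without control replicate 3, 23 without JFLX replicate 1, 32 without control replicate 2 and 35 without control replicate 4.

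Of the synaptic genes fixed before the data were examined, 10 stand among the listed genes, and 9 of them had higher values in JFLX. For presynaptic vesicle release, 5 of the 43 members are listed and 3 rose: the calcium sensor Syt7 by 0.95 ± 0.11, the vesicle SNARE Vamp1 by 0.86 ± 0.16 and the complexin Cplx1 by 0.65 ± 0.15 (SE, limma adjusted p = 0.00252, 0.0182 and 0.0448). Vamp1 has 2 listed probes of different sequence, of which the other, at 0.62, did not pass, and Cplx1 did not pass in 16 of the 19 other settings. Nsf, at 0.60 ± 0.15, and the vesicle protein Syp, at -0.46 ± 0.11, did not pass (adjusted p = 0.0632 and 0.0508). For the postsynaptic density, 5 of 39 members are listed, all with higher values, and 2 rose: the scaffold Dlg4 by 0.87 ± 0.11 (adjusted p = 0.00252) and the citron kinase Cit by 0.62 ± 0.14 (adjusted p = 0.0427), which did not pass in 16 of the 19 other settings. Camk2a at 0.56 ± 0.19, Shank2 at 0.50 ± 0.13 and Homer3 at 0.41 ± 0.15 did not pass. The higher to lower split of neither list differed from that of the other listed genes by Fisher's exact test, two-sided (adjusted p = 0.577 for 4 higher and 1 lower presynaptic genes, and 0.404 for 5 higher and 0 lower postsynaptic genes, over 6 lists tested). With 5 listed genes even 5 higher and 0 lower gave an unadjusted Fisher p of 0.0673. An all-higher list of this size could therefore not pass, and the test cannot decide the direction. Members enter these counts only because the authors called them changed on the same arrays, so the lists are not independent evidence of a direction.

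**Figure D2:**
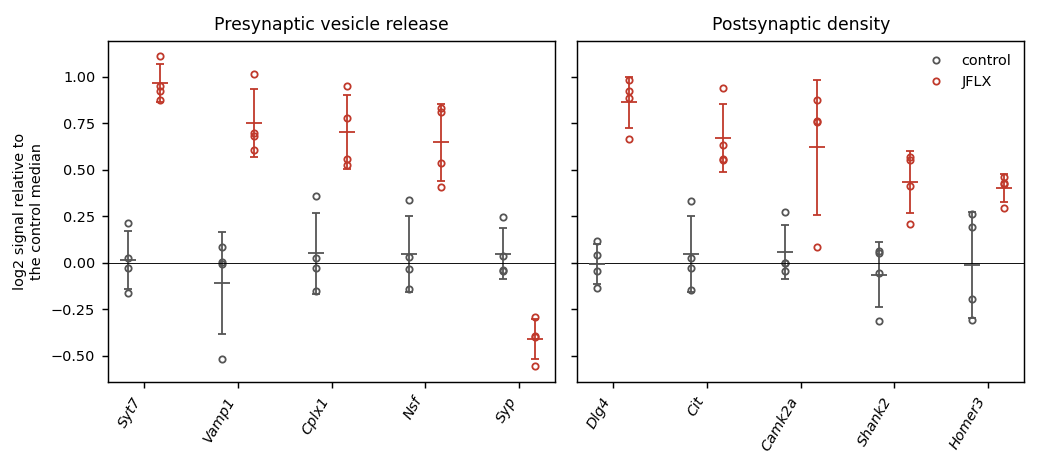
Log2 signal relative to the control median (y axis) for the listed members of the presynaptic and postsynaptic lists, with open circles for single arrays (4 control in grey, 4 JFLX in red) and bars for the group mean and SD. Syt7 (JFLX mean 0.97) and Dlg4 (JFLX mean 0.86) lie above all control arrays, and Syp lies below them.

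The glucocorticoid and stress axis list had 4 listed members of 25, of which 2 rose and 1 fell. Zbtb16, a transcription factor that responds to glucocorticoids, rose by 0.68 ± 0.09 (adjusted p = 0.00299), and Adcyap1r1, the receptor of the peptide PACAP, rose by 0.64 ± 0.14 (adjusted p = 0.0384). Fkbp4, a co-chaperone of the glucocorticoid receptor, fell by 0.42 ± 0.08 (adjusted p = 0.0229). Over the 19 other settings Adcyap1r1 did not pass in 15 and Fkbp4 in 12. The vasopressin receptor Avpr1a was detected on all 4 control arrays and on 0 JFLX arrays, with adjusted p = 0.202 and no fold. Scn2b, a sodium channel beta subunit, rose by 1.03 ± 0.16 (adjusted p = 0.00623), and the histone deacetylase Hdac11 rose by 0.57 ± 0.12 (adjusted p = 0.0255), but did not pass in 12 of the 19 other settings. The potassium channel genes Kcnab1 at 0.61 ± 0.21, Kcnc1 at 0.50 ± 0.14 and Kcng1 at 0.40 ± 0.13 did not pass. In axon guidance, 6 of 54 members are listed and 0 passed, with Nrp1 at 0.54 ± 0.13, Cdh8 at 0.50 ± 0.15, Unc5a at 0.45 ± 0.12 and Plxna2 at -0.43 ± 0.11. The chloride transporter Slc12a5 stood at 0.51 ± 0.13 and the autophagy receptor Sqstm1 at -0.53 ± 0.16, neither past the threshold. In the perineuronal net list, Hapln2 at 0.50 ± 0.17 and Chst11 at 0.51 ± 0.18 did not pass, and the proteoglycan Acan was detected on 3 control and 0 JFLX arrays (adjusted p = 0.0691). Per3 and Rpl28 were likewise detected on all 4 control arrays and on 0 JFLX arrays (adjusted p = 0.128 and 0.0586). Atf3, detected on 4 control and 0 JFLX arrays, did not pass (adjusted p = 0.201), and its groups overlapped.

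Markers of cell types gave few listed members. Glul, the glutamine synthetase of astrocytes, fell by 0.51 ± 0.11 (adjusted p = 0.0362), as the single astrocyte marker of 16 that is listed, and did not pass in 13 of the 19 other settings. For excitatory neurons Camk2a stood at 0.56 ± 0.19 and Neurod2 at -0.46 ± 0.15, and for interneurons Kcnc1 stood at 0.50 ± 0.14, none of them past the threshold. The endothelial marker Pecam1 had a difference of 0.68 ± 0.25 (adjusted p = 0.227). The platelet gene Ppbp passed (adjusted p = 0.0370), though not in 13 of the 19 other settings, and the fibroblast gene Lum did not (adjusted p = 0.114), and both were not well above background on any JFLX array. The other 6 marker lists, among them mature oligodendrocytes, oligodendrocyte precursors and microglia, had 0 listed members. Likewise 10 gene lists had 0 listed members, among them oxidative phosphorylation, mitochondrial biogenesis and sirtuins, serotonin signalling, glutamate receptors, neurotrophins, and innate immune genes. Since only listed probes carry names here, whether those genes are on the array and what values they had was not analysed here. A count adjusted over the list alone was not made, because the named members had already been selected by p on these arrays.

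The authors' deposited table holds 322 probes called higher and 260 called lower, while its read-me sheet gives 323 and 261. All 582 probes of the authors' deposited table had the same direction and an unadjusted p under 0.05 in limma, and 154 passed the adjusted threshold, 105 higher and 49 lower. The listed probes stand for 530 named genes, 291 higher and 239 lower, and the median fitted difference was 0.57 in the higher list and -0.59 in the lower list. The lower median includes the 117 probes detected on 0 JFLX arrays, most of which have no fold that can be given. The largest entries of the authors' deposited table that did not pass in limma were Abca4 at 1.51 ± 0.48 and the zinc finger gene Zfp521 at 1.30 ± 0.45 in the higher direction (SE, adjusted p = 0.143 and 0.190). In the lower direction Syne1, which anchors the nucleus to the cytoskeleton, stood at -1.35 ± 0.36 (adjusted p = 0.0775). Cavin1, a coat protein of caveolae, was detected on 1 of the 4 JFLX arrays and did not pass (adjusted p = 0.0539). Stom, Or52h7, Ybx2, Rel and Azgp1 were not well above background on any JFLX array and did not pass. Detection differed between the lists of the authors' deposited table: all 322 higher probes were detected on at least 3 arrays of both groups, against 119 of the 260 lower probes, and 117 lower probes were detected on 0 JFLX arrays. Elk1 is spotted 8 times in the higher list with differences from 0.58 to 1.06, and Galr2 5 times in the lower list with differences from -1.15 to -0.71.

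**Figure D3:**
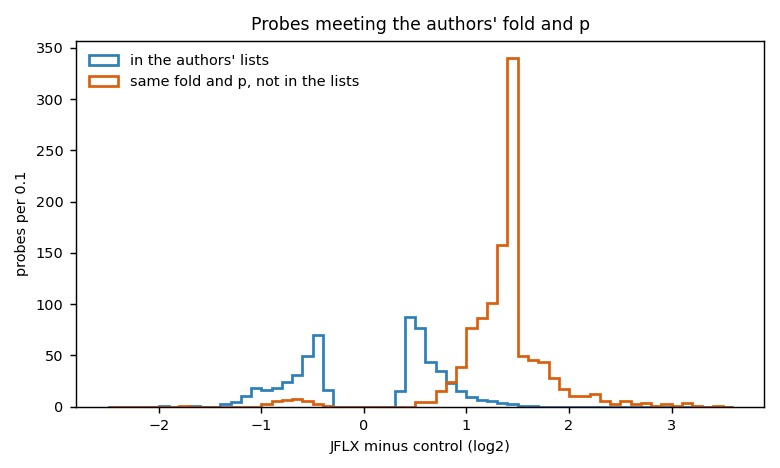
Number of probes per 0.1 (y axis) by their JFLX minus control difference on the log2 scale (x axis), for the 582 probes of the authors' lists (blue) and for the probes of the same fold and p outside the lists (orange). The listed higher probes have a median of 0.57, and the 1088 unlisted higher probes pile up around their median of 1.41.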

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

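Within the groups of 4, 12 values of named genes stood apart by Dixon's test among 148 groups tested, where chance gives about 1 in 20, or 7.4. Control replicate 4 held 5 of them. It was the lowest control array for Vamp1 (gap 0.855 of the range, value -0.52), Pecam1 (0.830, value -0.79), Hapln2 (0.850, value -0.38) and Azgp1 (0.885, value -1.49), and the highest for Pex2 (0.893, value 0.23). Control replicate 2 was the highest control array for Camk2a (0.859, value 0.28) and Zfp143 (0.862, value 0.34) and the lowest for Kcnc1 (0.896, value -0.26). Control replicate 1 was the lowest for Spock2 (0.906, value -0.17). JFLX replicate 4 was the lowest JFLX array for Camk2a (0.853, value 0.09 against 0.76 to 0.88) and Stk32c (0.840, value 1.08). JFLX replicate 2 was the highest for Kcnab1 (0.834, value 1.26 against 0.33 to 0.49). No explanation was tested for these single values.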

How the results depend on the processing

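The settings without unlisted probes and without shared-profile probes were chosen after seeing the data. No named gene changed direction over 1406 single values, but many settings could not change it. Trend and robust, the plain t-test, the replicate block and leaving out probes alone keep each difference. Centring on the median or 75th percentile shifts all differences by -0.05 or -0.19, and the smallest named one is 0.40. Of the 1406 values, 1043 stayed on their side of the threshold, 321 lost it and 42 gained it. Only the 43 named genes that passed in the main fit could lose it, and the other 31 could not. Main counts were 950 probes (896 higher, 54 lower), 1603 at unadjusted p and 1.5-fold, 154 of the authors' table, 12 list genes and 24 genes of the largest changes. Quantile normalization gave 0 probes, 0 higher, 0 lower, 989 at unadjusted p and 1.5-fold, 0 of the authors' table, 0 list genes and 0 of the 24. Without the unlisted probes these were 6, 6, 0, 490, 6, 0 and 6, and with quantile normalization as well 0, 0, 0, 235, 0, 0 and 0; without the shared-profile probes they were 296, 280 and 16 probes, 74 of the authors' table and 5 list genes. eBayes with trend and robust gave 0 lower probes, 44 of the authors' table, 4 list genes and 11 of the 24. Array quality weights gave 113 lower probes, 258 of the authors' table and 21 list genes. Centring on the 75th percentile gave 221 lower probes and the plain t-test 15 of the 24 genes. Of the 55 named genes of the authors' table with a fitted fold of at least 2, 28 passed, 17 of them higher. Over all 530 named genes 134 passed. Most of the lower genes among the 28 were detected on 0 JFLX arrays and have no fold given here. Leaving out probes with small p-values raises the other adjusted p-values by construction. Quantile normalization of these centred values gives the narrower control arrays and the wider JFLX arrays the same spread by construction. The cause was not tested for the other settings.

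With a replicate block 21 lower probes, 57 of the authors' table and 4 list genes passed, and 764 probes in all. Deviations of same-numbered arrays correlated from -0.28 to 0.40, and 3 of 8 arrays correlated best with their own number. A pairing by number was thus not shown, though so few arrays cannot exclude one. Leaving out single arrays gave 780 to 907 probes, 742 to 875 higher, 19 to 62 lower, 1523 to 1662 at unadjusted p and 1.5-fold, 77 to 134 of the authors' table, 5 to 14 list genes and 17 to 20 of the 24. The lowest counts of the authors' table came without control replicate 3 (77), control replicate 4 (86), JFLX replicate 1 (91), JFLX replicate 2 (95) and JFLX replicate 3 (95). Of list genes, 7 passed without control replicate 1, 5 without control replicate 3, 7 without control replicate 4, and 6, 5 and 7 without JFLX replicates 1, 2 and 3. Filters on dim probes, camera with an estimated correlation, fry and the choice of the brightest probe were not run, since levels are centred out and most probes are unnamed here. Signal over background limits the lower genes, of which 117 probes were detected on 0 JFLX arrays.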

Other observations

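Every test in this part was chosen after the result was seen. By the gene ontology terms of the authors' deposited table, 12 genes of kinase activity stand in its higher list and 0 in its lower list, and the one with the largest fold among them, Stk32c, passed in limma while Ptk2, Cdk19, Csnk1g1, Crk, Pfkfb3 and Pfkfb4 did not. Of 12 genes of protein serine/threonine kinase activity, 11 stand in the higher list, among them Gsk3a and Prkaca, which passed. Synaptic transmission had 7 genes in the higher list, among them Chrnb2, Dlg4 and Scn2b, which passed, and 1 in the lower list, Hcrtr1, which did not. Protein biosynthesis had 7 genes in the lower list, among them Eif4b, which passed, and Lars1, Mrpl15 and Mrpl17, which did not, and 2 in the higher list. Olfactory receptor activity had 1 gene in the higher and 10 in the lower list, most of them not well above background on any JFLX array. Detection could account for those counts, which was not tested for these genes, and they are not read further.

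None of the 92 terms passed Fisher's exact test, two-sided, against the split of the other annotated genes: the smallest adjusted p was 0.0731, for olfactory receptor activity and for kinase activity. In simulations on the 277 genes annotated with a molecular function this test called a planted term of 12 higher genes in 0.5% of 200 draws and one of 25 genes in 100%, and a random term in 1.5% and 4% of them. Among genes detected on at least 3 arrays of both groups, kinase activity had 12 higher and 0 lower genes (adjusted p = 0.994, 72 terms), and protein biosynthesis had 2 higher and 6 lower (adjusted p = 0.195), while olfactory receptor activity is not among those terms.

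The 1088 unlisted higher probes had a median difference of 1.41, with quartiles of 1.23 and 1.48, and 439 of them lay within 0.3 of 1 profile on all 8 arrays. That profile stood at -0.03, -0.34, 0.02 and 0.21 on the control arrays and at 1.46, 1.12, 1.68 and 1.16 on the JFLX arrays, and 30.1% of the probes lay within 0.15 of it, against 1.24% of the listed higher probes about their own median. The lowest detected signals, expressed on the deposited scale, lay 1.45 higher on the JFLX than on the control arrays, close to the 1.41 and as a signal floor that lies higher on the JFLX arrays could give. Listed probes nevertheless reached signals of 3.03, 2.44, 3.89 and 1.40 on the 4 JFLX columns of the authors' deposited table, against 3.77, 4.80, 4.27 and 2.73 on the control columns, so a floor was not seen among them. They were chosen by detection and direction, however, so they cannot show whether the unlisted probes sit on a floor. The cause of the profile stays open. Of the other 649 probes, 65.9% lie within 0.3 of the profile on at least 3 JFLX arrays. By the authors' stated rule these 649 would lack the detected flag on enough JFLX arrays, whereas their differences reached 3.45, above the gap of 1.45. A floor and genes raised in JFLX cannot be told apart for them, since their flags and intensities are not used here. Slide position stays confounded with treatment throughout.

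Of the 117 lower probes detected on 0 JFLX arrays, 111 had no bound above 1-fold, so a detection limit that lies higher on the JFLX arrays could account for their missing flags. The geometric mean of the lowest detected signals was 5.96 on the control arrays and 14.4 on the JFLX arrays. A fall in JFLX stays open for these genes: 6 probes had a bound above 1-fold, the largest for Afg2a, at least 1.39-fold lower (adjusted p = 0.124), and the rest lie too close to background to decide.

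Among the 35 splits of the arrays into 4 and 4, the real split gave 950 probes past the threshold, the highest other gave 192, and 1 split, the real one, reached that count. Ranking first is the smallest share that 35 splits can give, so this speaks against chance for the full count without excluding it. For probes at an unadjusted p under 0.05 the real split gave 2350 and the highest other 1718. With 1.5-fold as well the real split gave 1603 and the highest other 798, each time with 1 split as large. With the unlisted probes left out the real split gave 6 and the highest other 200, but those probes were chosen by their fold and p in the real split. This is therefore no test of chance, and whether chance gave the remaining calls stays open. The split with 200 sets control replicates 1 and 3 with JFLX replicates 3 and 4 against the rest.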
